A study of Mus musculus with 12 samples.

How the data were processed

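The series holds chromatin immunoprecipitation sequencing (ChIP-seq) of FOXA1 and FOXA2 in colonic crypts of wild type C57BL/6 male mice, 3 months old per the labels. FOXA1 and FOXA2 are forkhead transcription factors. ChIP-seq sequences the DNA fragments that an antibody against a protein pulls down from cross-linked chromatin. The labels give 4 FOXA1 and 6 FOXA2 libraries and 2 input libraries. Input is chromatin sequenced without antibody. Per the labels' protocols, fragments of about 200 bp were selected and amplified by 18 cycles of PCR. Each antibody library has 1 peak list, and the input libraries were not analysed here except through the input columns of those lists.

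Per the submitters' processing notes, HOMER 4.11.1 and the mouse build mm9 were used. The aligner is not given in the sources used here. Per the file headers, peaks were called in HOMER's factor style for each library on its own, against an input tag directory of the same name in every header, and replicates were not pooled. Per the file headers, a peak had to pass a false discovery rate of 0.001. It also needed at least 4-fold more tags than the scaled input and than the surrounding 10 kb, with a Poisson p of 0.0001 for each. The total tags at a peak are a count deposited by the authors without normalization. The normalized tag count is a signal that the authors scaled to 10000000 tags per library, per the file headers. The input tags at a peak are a signal that the authors scaled to the depth of the antibody library. The focus ratio is a fraction deposited by the authors, which is lower where the tags of a peak are spread away from 1 centre. The peak score, the fold over input and the fold over the surroundings are the authors' values for each peak. The score and each fold as deposited were used only to rank, filter or describe peaks within their own list, except that the fold over input of a site is given as a median over its peaks. Each p-value in the lists is the authors' Poisson p-value for a peak and was not used in any test here. Peak widths were fixed within each list and ranged from 147 to 171 bp between lists, so normalized tags of different lists cover slightly different lengths.

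Total tags per library ranged from 11954549 to 30992727 (11.95 to 30.99 M), per the file headers. Each tag directory name in the headers ends in 2 or 4, and the headers do not say what this number stands for. It is called the directory number here, and comparisons were repeated within each number because depth differed between the numbers. The labels do not say that the libraries came from separate animals. The p-values therefore measure the spread between these samples only, and that spread may be technical.

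From the lists, overlap between 2 libraries was counted as peaks of the shorter list that shared at least 1 bp with the other, as a percent of the shorter list. Peaks of all 10 lists that shared at least 1 bp were merged into sites, and a site was called reproducible for an antibody when at least 2 of its libraries had a peak there. The difference in log10 peak number, the difference in mean overlap within and between antibodies, and the number of sites reproducible with one antibody only were each tested by exact permutation over all 210 splits of 10 libraries into 4 and 6. Detection at each site was tested with a two-sided Fisher's exact test and Benjamini-Hochberg adjustment at 0.05. Shares of sites have 95% Wilson intervals, which cover counting error only and treat sites as independent. Chance overlap was measured by moving sites by 5 kb and by 1000 uniform placements.

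The rule for the sites to name was fixed before the data were examined, and the sites themselves were then picked from the data. It took the 10 sites with a peak in the most libraries, ties going to the higher mean percentile of score within the lists. The 5 sites leaning to each antibody with the smallest Fisher p were added, ties going to the larger difference in the share of libraries. Planned comparisons of genomic location, gene lists and the forkhead motif were not run. They need the mm9 genome or its annotation, which was not used here. The gene table at hand is of GRCm38.p6, and the last peak on chromosome 1 ends at 196841038, 1549599 bp beyond the last gene of that table. Sites are therefore given by mm9 coordinates alone, and whether a site lies in a gene, exon, intron or promoter is not reported.

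The alternatives tried were leaving out each library, at least 8-fold over input, the 300 highest-scoring peaks, stricter overlap, another similarity measure, other numbers of libraries per site, equal numbers of libraries, other sets of sites tested, the linear scale and a replicate block. Alternatives by directory number, by fold over the surrounding 10 kb, by leaving out peaks of high input and by leaving out FOXA2 replicates 5 and 6 were added after the data were seen.

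The computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. They were tested on simulated data for 10 libraries. Merging recovered 3830 of 3830 simulated sites. These were spaced far apart compared with the width of a peak, so the merging of adjacent sites was not tested. With 200 planted FOXA1-only sites among 4200, the split test of sites with one antibody only gave an exact permutation p of 0.290 (0.0571 with 1000 planted, 0.0476 with 2000) and Fisher's test with adjustment called 0 sites. The overlap test gave an exact permutation p of 0.00476, the smallest possible, with 500 planted sites. Planted sites were given at a high rate to every FOXA1 library, whatever its list length. As FOXA1 replicate 4 has only 462 peaks in all, this may overstate the power of the overlap test. Because the split test missed planted sets, shuffles that keep the number of sites per library and of libraries per site were added. With 200 planted sites they gave a mean of 173 FOXA1-only sites and at most 203, against 333 in the simulated lists. With 0 planted they gave a mean of 126 and at most 149, against 135. In 60 simulations with no antibody effect, 0 of the overlap tests and 0 of the split tests reached 0.05. All 60 took their rates from the real list lengths and tested the real split alone. They may mean that this split rarely reaches a small p, and they do not show that the tests are calibrated.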

Results

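FOXA1 and FOXA2 binding was measured by ChIP-seq in colonic crypts, the epithelial glands that hold the stem and secretory cells of the colon, of wild type male mice. The data comprised 4 FOXA1 and 6 FOXA2 libraries, each with its own peak list, and 20322 peaks in all, 9258 with FOXA1 and 11064 with FOXA2. Total tags averaged 21.7 ± 10.1 M per FOXA1 library (SD, n = 4) and 16.8 ± 5.40 M per FOXA2 library (SD, n = 6). Depth differed between the directory numbers, with 11.95 to 15.35 M tags in the 6 libraries of number 2 and 23.2 to 30.99 M in the 4 libraries of number 4. Number 2 comprised FOXA1 replicates 1 and 2 and FOXA2 replicates 1 to 4, and number 4 the rest.

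The first comparison asked whether the antibodies differed in the number of binding sites they recovered. Peak number varied widely within each antibody. FOXA1 replicates 1 to 4 had 2386, 5159, 1251 and 462 peaks, and FOXA2 replicates 1 to 6 had 761, 2088, 3706, 120, 2064 and 2325. The deepest library, FOXA1 replicate 3, had 1251 peaks from 30.99 M tags, whereas FOXA1 replicate 2 had 5159 from 12.3 M. The mean log10 peak number was 3.21 ± 0.444 with FOXA1 (SD, n = 4) and 3.09 ± 0.543 with FOXA2 (SD, n = 6), a 1.33-fold difference. It was smaller than the spread between libraries (two-sided exact permutation p = 0.748, adjusted 0.935 over 5 measures per library). The share of tags in peaks was 0.478 ± 0.352% with FOXA1 and 0.402 ± 0.161% with FOXA2 (SD, n = 4 and 6, exact permutation p = 0.676, adjusted 0.935).

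A few regions with many tags in the input held much of that share. In each library 3 to 8 peaks had at least 20 scaled input tags, and they held 15.6% of the tags in peaks in FOXA2 replicate 3 and 90.7% in FOXA2 replicate 4. Without them the share of tags in peaks was 0.291 ± 0.307% with FOXA1 and 0.233 ± 0.184% with FOXA2 (SD, n = 4 and 6, exact permutation p = 0.686, adjusted 0.935). The authors' comparison with input had removed 37.4 ± 25.4% of putative peaks with FOXA1 and 37.7 ± 23.1% with FOXA2 (SD, n = 4 and 6, exact permutation p = 0.981). Total tags did not separate the antibodies either (exact permutation p = 0.324, adjusted 0.935). The difference in log10 peak number, 0.125 over all libraries, was 0.583 within directory number 2 and -0.460 within number 4 (exact permutation p = 0.333 in each). Within the numbers 2 libraries are set against 4 and against 2, where the smallest p is 0.0667 and 0.333, so neither can pass 0.05. It was -0.0419 without FOXA1 replicate 2 and -0.0772 without FOXA2 replicate 4.

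**Figure D1:**
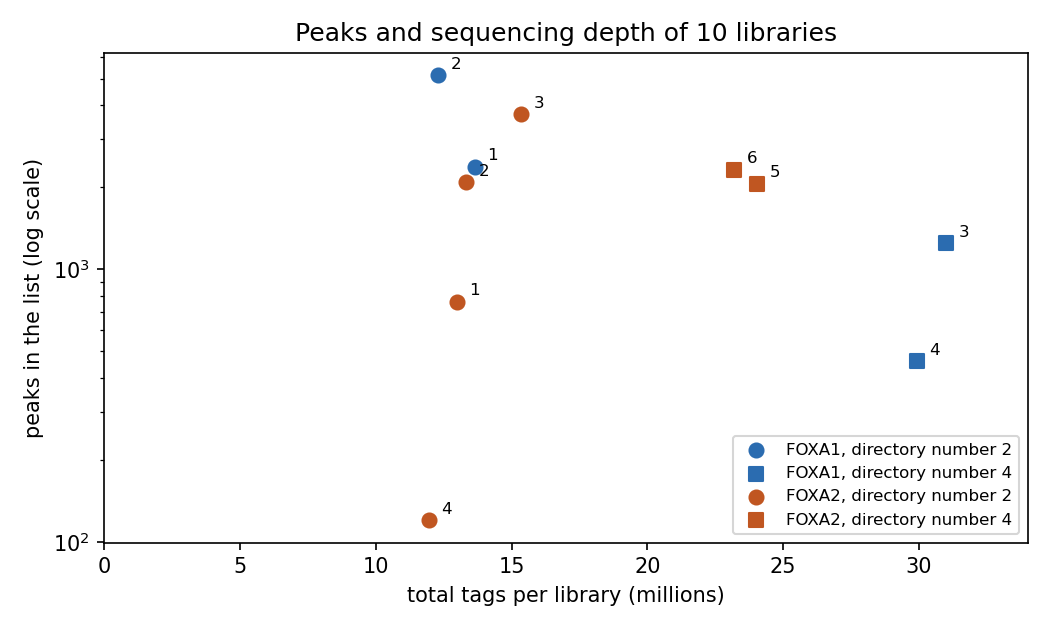
Peaks in each list (log scale) against total tags (M) for the 4 FOXA1 and 6 FOXA2 libraries, each point labelled with its replicate number and shaped by its directory number. Peak number ranged from 120 to 5159 and from 462 to 2325 in the 4 deeper libraries of number 4.

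The second comparison asked whether libraries of one antibody shared more sites with each other than with libraries of the other antibody. By percent of the shorter list, FOXA1 and FOXA2 lists overlapped each other less on average than FOXA1 lists did and more than FOXA2 lists did. Overlap averaged 57.3 ± 21.6% of the shorter list between antibodies (SD, 24 pairs), 72.2 ± 11.8% within FOXA1 (6 pairs) and 46.3 ± 22.3% within FOXA2 (15 pairs). FOXA2 replicate 4 overlapped every other library by 13.3% to 18.3%. Without it the averages were 65.6 ± 11.8% between antibodies (SD, 20 pairs) and 60.7 ± 9.26% within FOXA2 (10 pairs). The highest overlap between antibodies was 85.6%, for FOXA2 replicate 2 with FOXA1 replicate 2. A percent of the shorter list also depends on the lengths of the lists compared. Within FOXA1 it was highest, 86.1%, for replicates 2 and 4, the longest and shortest FOXA1 lists. It was lowest, 52.4%, for FOXA1 replicates 1 and 3. The averages were not adjusted for list length, so their order may in part reflect it.

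Over all pairs of one antibody the mean was 53.7%, lower than the 57.3% between antibodies. This mean counts 15 FOXA2 pairs and 6 FOXA1 pairs, so it leans to the lower FOXA2 overlap. The sign of the difference over all libraries depends on that weighting. Over all 10 libraries, overlap thus did not order the lists by antibody (difference of -3.66 points, one-sided exact permutation p = 0.757). The difference was -9.13 points within directory number 2 and -6.65 within number 4 (one-sided exact permutation p = 0.800 and p = 1). The value within number 2 includes FOXA2 replicate 4, which overlapped every other library by at most 18.3%. With only FOXA2 replicate 4 left out of all libraries, the difference was -0.567 points. Its direction turned when FOXA2 replicates 5 and 6 were left out, to 3.62 points (57.0% within and 53.4% between antibodies, one-sided exact permutation p = 0.0571). With those left out, both antibodies have the same number of libraries and of pairs.

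**Figure D2:**
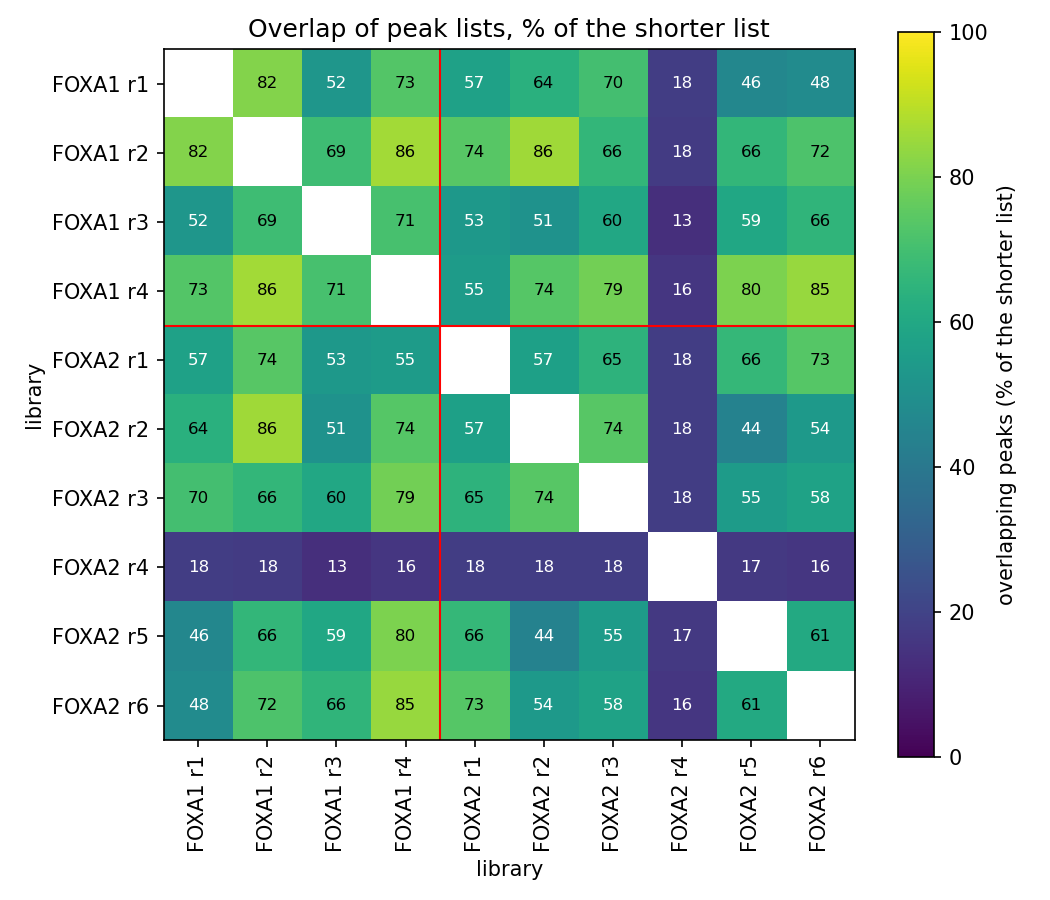
Overlapping peaks as a percent of the shorter list for each pair of libraries, with replicates labelled r1 to r6 and red lines dividing the FOXA1 from the FOXA2 libraries. The mean between antibodies (57.3%) lies between those within FOXA1 (72.2%) and within FOXA2 (46.3%), and FOXA2 replicate 4 lies between 13.3% and 18.3% with every other library.

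The third comparison described the sites that each antibody recovered reproducibly and how far they coincided. With 2 libraries asked for per site, most reproducible sites of each antibody were reproducible with the other as well. With 3 asked for, 91.1% of 732 FOXA1 sites but 46.8% of 1424 FOXA2 sites were. The peaks of all lists merged into 8424 sites, of which 4493 (53.3%, 95% Wilson interval 52.3 to 54.4) had a peak in 1 library. Reproducible sites numbered 2236 with FOXA1 and 2553 with FOXA2, and 1671 were reproducible with both. These 1671 were 74.7% of the FOXA1 sites (72.9 to 76.5) and 65.5% of the FOXA2 sites (63.6 to 67.3). Of the FOXA1 sites, 91.6% (90.4 to 92.7) had a peak in at least 1 FOXA2 library, and 88.8% of the FOXA2 sites (87.5 to 89.96) had a peak in at least 1 FOXA1 library.

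These counts compare 4 with 6 libraries. Over the 15 choices of 4 FOXA2 libraries, FOXA2 had 1757 sites on average, fewer than FOXA1. The shared sites were then 57.1% of the FOXA1 and 72.7% of the FOXA2 sites. Most of these choices include FOXA2 replicate 4, which has 120 peaks and adds few sites. Leaving out 1 of the other FOXA2 libraries, so that 4 remain beside replicate 4, gave 1770 to 2488 FOXA2 sites. Shared sites were then 55.7% to 73.8% of the FOXA1 and 66.4% to 72.4% of the FOXA2 sites.

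The sites detected most often with one antibody were nearly all sites of the other. Of 279 sites with a peak in all 4 FOXA1 libraries, 278 were reproducible with FOXA2. Of 367 sites with a peak in 5 or 6 FOXA2 libraries, 353 were reproducible with FOXA1 (96.2%, 93.7 to 97.7). Moving the FOXA2 sites by 5 kb to either side left 4 and 5 FOXA1 sites overlapped, and uniform placement left a median of 1 and at most 5. Sites reproducible with both antibodies ranked higher in their lists, at a median score percentile of 62.8, than sites with FOXA1 and no FOXA2 peak (36.9) or with FOXA2 and no FOXA1 peak (36.8). These classes also differ in the number of libraries, and the 813 sites with a peak in 1 library of each antibody had a median percentile of 36.98. Sites of 1 library had a median percentile of 16.2. The FOXA1 count rested on replicates 1 and 2. It was 953 without replicate 1, with 874 sites shared, which were 91.7% of the FOXA1 and 34.3% of the FOXA2 sites. It was 755 without replicate 2, with 730 shared, which were 96.7% of the FOXA1 and 28.6% of the FOXA2 sites.

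**Figure D3:**
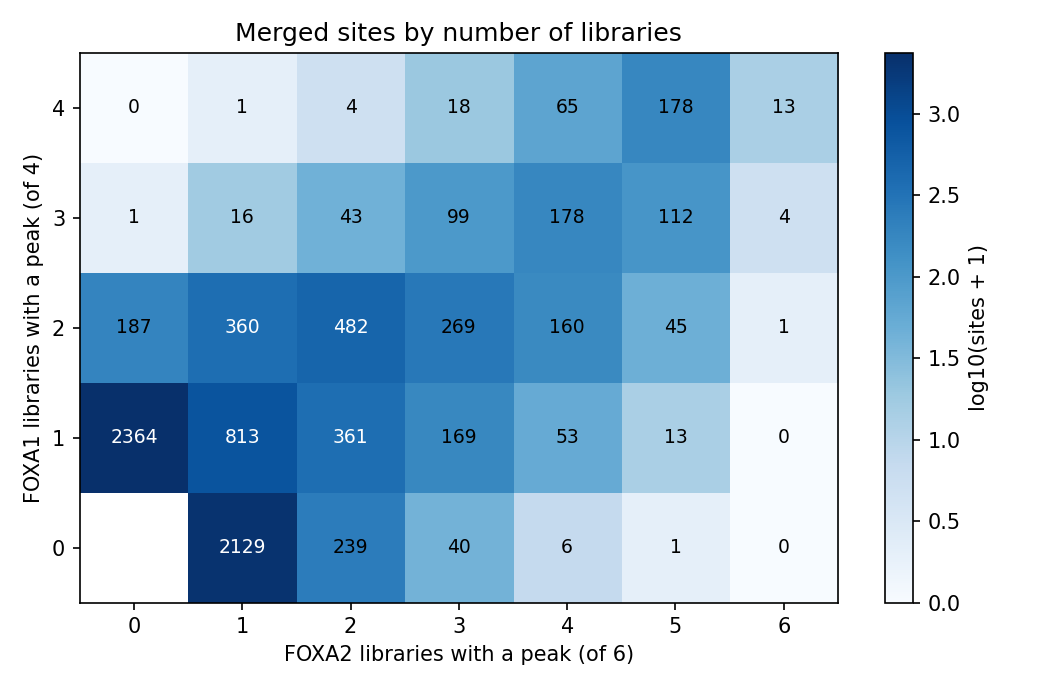
Number of merged sites by how many of the 4 FOXA1 libraries (vertical) and of the 6 FOXA2 libraries (horizontal) had a peak there, with colour giving log10 of sites plus 1. Sites found in 3 or 4 FOXA1 libraries had FOXA2 peaks as well, save 1 site, and 13 sites had a peak in all 10 libraries.

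At the 10 sites named for having a peak in every library, tag levels of the antibodies overlapped. The site ranking highest in the lists apart from high-input regions was on chromosome 13 (mm9 34338829 to 34339009), with 50.5 ± 38.3 normalized tags with FOXA1 (SD, n = 4) and 42.6 ± 19.3 with FOXA2 (SD, n = 6). Its median fold over input was 68.7. The next were on chromosome 5 (68322978 to 68323165), with 23.6 ± 11.1 and 23.4 ± 10.3 normalized tags, and on chromosome 16 (90821420 to 90821627), with 33.0 ± 26.5 and 29.6 ± 13.6. The site on chromosome 10 (79447630 to 79447837) had 23.3 ± 17.8 and 22.6 ± 11.5, and that on chromosome 13 at 54526670 to 54526891 had 23.7 ± 15.6 and 21.8 ± 7.06. Those on chromosome 4 (46548123 to 46548304) and chromosome 5 (64795123 to 64795342) had 17.0 ± 9.01 and 21.6 ± 5.42, and 16.4 ± 9.43 and 19.7 ± 8.34. The site on chromosome 1 (90851435 to 90851663) had 16.2 ± 9.97 and 14.7 ± 3.23.

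The remaining 2 of the 10 differed in kind. The site on chromosome 9 (3015237 to 3015407) held 668 ± 45.9 normalized tags with FOXA1 and 649 ± 43.6 with FOXA2 (SD, n = 4 and 6), but also a median of 179 scaled input tags, and its median fold over input was 5.38. The site on chromosome 7 (52924792 to 52925115) ranged from 7.33 normalized tags in FOXA2 replicate 6 to 214 in FOXA2 replicate 3, and its peaks had a low focus ratio, 0.641 at the median. The FOXA1 and FOXA2 ranges of normalized tags overlapped at each of the 10 sites. The sites were chosen for a peak in every library, and tags were not adjusted for the enrichment of each library. This overlap therefore says little about the antibodies.

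**Figure D4:**
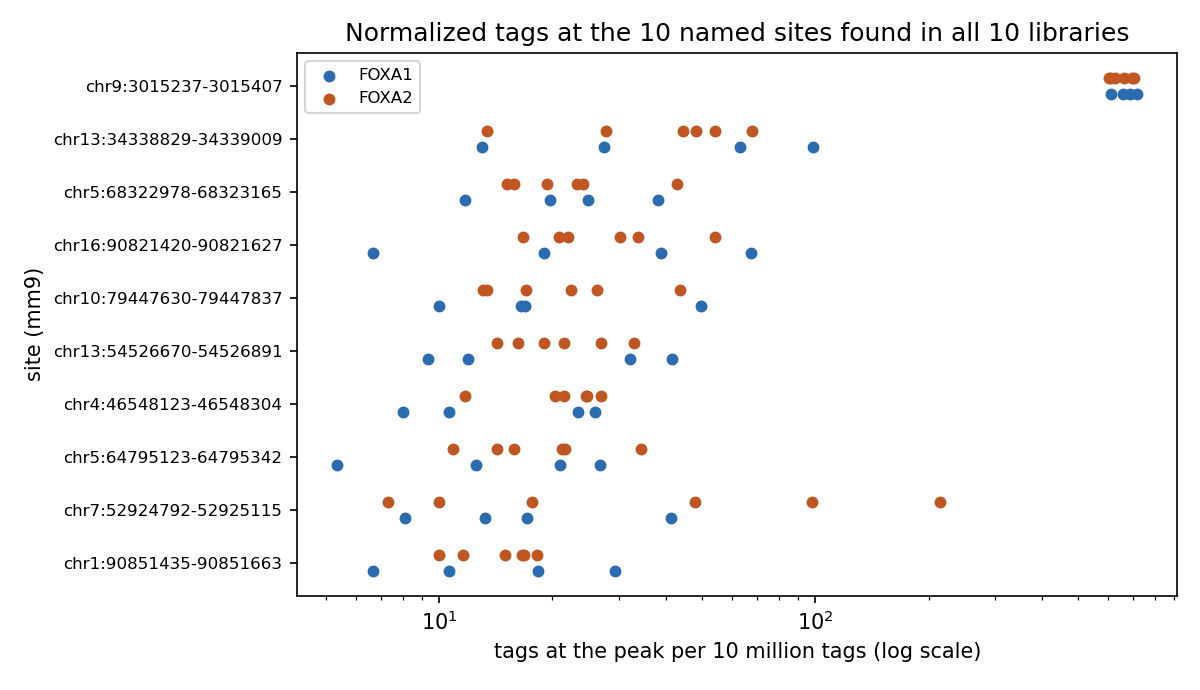
Tags at the peak per 10000000 tags (log scale) in each library at the 10 named sites with a peak in all libraries, blue for the 4 FOXA1 and orange for the 6 FOXA2 libraries. The antibodies overlap at every site, and the top site, on chromosome 9, is a region of high input.

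The fourth comparison asked whether some sites belonged to one antibody only. Such sites were mostly detected in the smallest number of libraries that counts as reproducible. With FOXA1, 188 sites were reproducible and had no FOXA2 peak, of which 187 were found in exactly 2 libraries, 162 of them in replicates 1 and 2. With FOXA2, 286 sites had no FOXA1 peak, of which 239 were found in exactly 2 libraries and 7 in 4 or more. Which antibody had more depended on the libraries. Over the 15 choices of 4 FOXA2 libraries there were 348.9 FOXA1-only and 134.6 FOXA2-only sites on average. Most of these choices include FOXA2 replicate 4, which has 120 peaks. Without FOXA2 replicate 3 there were 417 and 159, and without FOXA2 replicate 1 there were 190 and 263. Without FOXA1 replicate 2 there were 5 and 799. The total of 474 was within what other splits of the libraries gave, a median of 647.5 and a range of 345 to 2689 (one-sided exact permutation p = 0.738). It was 804 without FOXA1 replicate 2. Within directory number 2 it was 324, 241 with FOXA1 and 83 with FOXA2, against a median of 590 over splits (exact permutation p = 0.800). Within number 4 it was 515, of which 513 were FOXA2 sites, against a median of 120, and the p of 0.333 was the smallest that exact permutation of 2 against 2 allows. Shuffles within number 4 that keep the totals per library and per site gave 380 to 438 FOXA2-only sites, fewer than the 513 seen. On simulated lists the split test missed 200, 500 and 1000 planted sites and passed with 2000. By itself it cannot exclude sets of up to 1000 sites. The counts argue against sets of the simulated kind, which were planted at a high rate in every FOXA1 library. Of 200 planted, 199 were in 2 or more FOXA1 libraries. Here 188 FOXA1-only sites were seen, 1 of them in 3 or 4 libraries. FOXA1 replicates 3 and 4 have only 1251 and 462 peaks in all, which itself limits sites in 3 or 4 FOXA1 libraries. The counts therefore say little about FOXA1 sites that these short lists would miss. Sites detected in fewer libraries and FOXA2-only sites were not simulated.

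The fifth comparison tested each site for detection with one antibody more than the other. The sites leaning most to FOXA1 lay on chromosome 2 (146402359 to 146402529), with a peak in 3 of 4 FOXA1 and 0 of 6 FOXA2 libraries, and on chromosome 11 (81931940 to 81932136), in 4 and 1. Sites on chromosome 5 (137443136 to 137443330), chromosome 11 (48686593 to 48686954) and chromosome 4 (59730372 to 59730586) had peaks in 4 FOXA1 and 2 FOXA2 libraries. The chromosome 11 site at 48686593 lies beside another with very uneven tags between libraries. The site leaning most to FOXA2 was on chromosome 2 (169478790 to 169479065), in 0 of 4 FOXA1 and 5 of 6 FOXA2 libraries, with 7.33 to 14.6 normalized tags where it was detected. Sites on chromosome 10 (89820486 to 89820703), chromosome 1 (65224007 to 65224209), chromosome 7 (86447390 to 86447578) and chromosome 3 (108279931 to 108280108) were in 0 FOXA1 and 4 FOXA2 libraries.

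None of these differences passed the test. Of 3931 sites with a peak in at least 2 libraries, 0 passed Fisher's exact test with Benjamini-Hochberg adjustment, and 3 had an unadjusted p under 0.05, the smallest being 0.0333. With 4 against 6 libraries the smallest exact p is 0.00476, and at least 375 sites fully separated by antibody would have been needed to pass the adjusted threshold. There were 0 such sites.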

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

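The tests of the shared input, of the directory number without FOXA2 replicate 4, of shuffled lists and of the uneven sites were chosen after the results were seen. Of 38 groups of values examined for a library standing far from the others of its antibody, 3 held one, where chance gives about 1 in 20 (1.9). Both measures of list overlap set FOXA2 replicate 4 apart. At the site on chromosome 5 (68322978 to 68323165), FOXA2 replicate 3 had 43 normalized tags, against 15.1 to 24.1 in the other FOXA2 libraries.

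In FOXA2 replicate 4, 22.5% of the 120 peaks lay at a site of another library, against 74.2% to 93.0% in the other FOXA2 libraries, and its median overlap was 17.5% against 56.8% to 64.8%. Lower depth was argued against: scores of the other 5 libraries of directory number 2 scaled to its tag total left at least 518 peaks. Weak enrichment stays open. Of the sites of all 9 other libraries, 8 of the 95 stronger and 5 of the 95 weaker were called in it (Fisher's exact p = 0.567). Keeping only the strongest sites would not by itself give this list, as only 22.5% of its peaks lay at a site of another library. Apart from high-input regions, 0.0190% of its tags lay in peaks, against 0.106% to 0.560% in the other FOXA2 libraries. No biological explanation was tested, because it shares its labels with those libraries.

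FOXA1 and FOXA2 lists were not separated by overlap over all libraries, though the difference was 3.62 points without FOXA2 replicates 5 and 6 (exact permutation p = 0.0571). Shared troughs of the input were argued against as the cause, because median scaled input tags at sites of both antibodies were above the tags expected per peak in 10 of 10 libraries, by 1.17 to 1.86 times. Overlap within directory numbers exceeded that between them by 3.39 points with all libraries (one-sided exact permutation p = 0.305) and by 7.94 points without FOXA2 replicate 4 (p = 0.0159, exact, 126 splits), so the number, or what goes with it such as depth, may order the lists in part. By antibody the difference over the same 9 libraries was -0.567 points (exact permutation p = 0.643). Shared binding of both factors, and recognition of both by either antibody, remain open and were not tested. Other sources common to both antibodies were not tested either, and the raised input at these sites was left unexplained. Power was examined on simulated lists only.

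Over all libraries, chance cannot be excluded for the counts of sites with one antibody. Of 100 splits of the libraries drawn, the real one included, 99 gave at least the 3 sites seen at an unadjusted Fisher p under 0.05, with 866 as the highest other, and 72 gave at least the 474 sites with one side only, with 2169 as the highest. The split with 866 set FOXA1 replicates 1 and 2 and FOXA2 replicates 2 and 3 against the rest, and it exceeded the highest count of the same splits in 100 shuffles that keep the totals per library and per site (379 to 449). Differences in list length alone therefore did not give it, and the samples have some structure that crosses the antibodies. Its origin was not tested, but all 4 libraries named are of directory number 2. The other libraries of number 2, FOXA2 replicates 1 and 4, had 761 and 120 peaks. The number, or what goes with it, may thus have a part in this structure. The split by directory number gave 19 and 1615 sites. In shuffles of all libraries, 79 of 100 had at least the 188 FOXA1-only sites seen and 80 at least the 286 FOXA2-only sites, with ranges of 156 to 227 and 255 to 330. Within directory number 2 the 241 FOXA1-only and 83 FOXA2-only sites lay within the range of the shuffles (192 to 243 and 75 to 120), but only 2 of 100 had at least as many FOXA1-only sites, and 96 at least as many FOXA2-only sites. Within number 4 the 513 FOXA2-only sites exceeded them (380 to 438), and the 2 FOXA1-only sites did not (1 to 10). Sites peculiar to FOXA2 and a likeness of these 2 libraries for another reason cannot be told apart there, with 2 libraries per antibody. Within number 2, 3 of 15 pairs of libraries exceeded their shuffles, among them FOXA1 replicate 2 with FOXA2 replicates 1 and 2.

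Among 614 sites with a peak in at least 7 libraries, the 5 with the most uneven tags had an SD between libraries, each centred, of 1.32 to 1.81 (log2), against a median of 0.41, and 4 of the 5 lay within 2 kb of another site. They lay on chromosomes 11 (48686270 to 48686520, 14.7 to 1354 normalized tags), 7 (52924792 to 52925115, 52925372 to 52925799 and 148875743 to 148876111) and 14 (99694939 to 99695598). Copies also present in the input were argued against by input tags 1.08 times those of the other 609 sites, whereas a single enrichment level per library could not be tested on sites chosen after centring each library (FOXA2 replicate 4 was among the 3 highest libraries at 4 of the 5). Added fragments such as PCR products may be a source, as the median focus ratio was 0.667 against 0.89 at the other sites, and 0 percent of those were as low. The ratio is low wherever tags spread from 1 centre, which may also hold for adjacent peaks, so it does not single out such fragments. Binding that differed between the samples was not tested and stays open.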

How the results depend on the processing

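The settings by directory number, by fold over the surrounding 10 kb, by leaving out high-input peaks and by leaving out FOXA2 replicates 5 and 6 were chosen after the results were seen. Leaving out each library gave a log10 peak difference of -0.0772 to 0.307 (-0.0419 without FOXA1 replicate 2, -0.0772 without FOXA2 replicate 4), an overlap difference of -8.47 to -0.0903 points, 755 to 2237 FOXA1 sites, 1770 to 2554 FOXA2 sites, 730 to 1671 sites of both, 355 to 804 sites of one antibody only and 0 to 0 sites past the adjusted Fisher test (4 to 23 unadjusted). The planned tests of the antibodies did not pass 0.05 under any setting, but the tests by directory number and with the replicate block could not have passed, and the adjusted Fisher test needed at least 375 fully separated sites with all libraries. Within directory number 4 the peak difference was -0.460. With the 300 highest-scoring peaks, where FOXA2 replicate 4 has too few and was left out, the counts were 314, 376, 254 and 67. Leaving out that library alone gave 2237, 2551, 1671 and 472, so the shorter lists made the change. Peak numbers are then equal and give no comparison. With at least 3 libraries per site they were 732, 1424, 667 and 48, and with at least 50% of the libraries FOXA2 had 1424, because more detections were asked for. With the replicate block over numbers 1 to 4 the peak difference was 0.251 (exact sign-flip p = 0.375) and the overlap difference 3.62 points (exact p = 0.125, the smallest it allows), where FOXA2 replicates 5 and 6 do not enter. Without the block the same 8 libraries gave 3.62 too (exact permutation p = 0.0571). Leaving out FOXA2 replicates 5 and 6 thus turned the direction, and it also made the pairs per antibody equal in number. Same-numbered lists overlapped 1.77 points more than differently numbered ones (exact permutation p = 0.417). Deviations of the paired numbers correlated at -0.106, 0.0582, -0.198 and -0.0141, so no pairing by number was seen. A shared animal or preparation cannot be excluded by so few pairs. Replicates 3 and 4 of the antibodies also differ in directory number, which may hide a pairing. Genomic location, gene lists and the forkhead motif were not run. What depth limits was not tested: 53.3% of sites were in 1 library, but peak number did not differ detectably by directory number (exact permutation p = 0.905).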

Other observations

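The distance between neighbouring sites and its comparison with uniform placement, and the rank correlation by directory number, were chosen after the results were seen. Sites with a peak in at least 2 libraries were spread over the 19 autosomes at 1.604 ± 0.263 per Mb (SD over autosomes, with lengths taken from the last peak of each). Chromosome 11 had 2.33 per Mb and chromosome 19 had 2.20, and chromosome 3 the fewest, 1.28. The X chromosome had 24 sites or 0.144 per Mb, against 1.587 over the autosomes pooled. Per library, the X to autosome density ratio was 0.0321 to 0.138.

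A candidate explanation is that there is one X copy in males, which lowers the tags of every X site. Peaks on autosomes that would stay above the lowest score of their list at 50% of their score made up 7.38% to 22.1%, and the X ratio was below that share in 8 of 10 libraries, short of the 9 that would have argued against it. The exceptions were FOXA2 replicates 1 and 4, with 7 and 1 X peaks. The X copy number and a lower density of sites on the X cannot be told apart here.

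Sites clustered along the chromosomes. Of 3931 sites in at least 2 libraries, 16.9% had another within 10 kb, against 3.24% on average and 4.63% at most in 1000 uniform placements. The densest 100 kb window was on chromosome 1 (132700001 to 132800000), with 6 sites from 132700134 to 132737805, each in at most 4 libraries. A window on chromosome 8 (63800001 to 63900000) had 5 sites, 3 of them in at least 5 libraries, and one on chromosome 13 (32400001 to 32500000) had 5, of which 1 was in 9 libraries. Median scaled input tags were 1.13, 0.95 and 1 in these windows. A window on chromosome 7 (52900001 to 53000000) also had 5 sites, 2 of them with very uneven tags between libraries (52924792 to 52925115 and 52925372 to 52925799), with a higher median of 1.5 scaled input tags.

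Peak centres of FOXA1 and FOXA2 lay about as close together as those of one antibody. The median distance between peak centres at shared sites differed by 0.610 bp, 18.5 bp within antibodies and 19.1 bp between them (two-sided exact permutation p = 0.400). Of 190 sites with a peak in each of the 9 libraries other than FOXA2 replicate 4, 1 of high input and 1 with very uneven tags were left out. Over the other 188, Spearman's rho of tags across sites averaged 0.395 within antibodies and 0.447 between them (one-sided exact permutation p = 0.944 over libraries, sites not being independent replicates). By directory number it averaged 0.516 within and 0.350 between (one-sided exact permutation p = 0.0159). After centring each library, the FOXA1 and FOXA2 libraries did not overlap in relative tags at 2 of the 188 sites, 1 higher with each antibody, where chance gives 1.59% or 2.98 sites. At least as many were found in 81 of 126 splits of the libraries, with 30 as the highest.

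Peaks of higher score recurred more often. The top 25% of scores lay at a site of another library more often than the bottom 25% in 10 of 10 libraries, at 60% to 99.8% against 13.3% to 81.8%. The value of 60% was that of FOXA2 replicate 4, and the next lowest was 97.4%, in FOXA1 replicate 2.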
